A study of Mus musculus with 24 samples.

How the data were processed

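Libraries came from 4 brain regions (cerebellum, cortex, hippocampus, olfactory bulb) of Cdr1as-knockout and wild-type C57BL/6 mice, with 3 per region and genotype and 24 in all. Per the labels, RNA was extracted with TRIzol and poly(A)-selected, and the library kit kept the strand of the mRNA. Each library was counted as 1 replicate. The labels do not say whether the 3 replicates of a group are separate animals, nor whether libraries that share a genotype and a number in different regions came from the same animal.

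The deposited values are raw read counts per gene, 1 table per library, as whole numbers. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, aligned to mouse assembly mm9 with STAR 2.5.1b and counted with HTSeq 0.6.1p1. Whether the counting used the strand is not stated in the sources used here, so overlapping and antisense genes are reported as uncertain. Each table held 37626 lines, of which 5 were summaries naming no gene and 37621 were features, including Cdr1asG, a feature the authors added for the Cdr1as locus. No table gave coordinates for Cdr1asG, so it could not be placed against the annotation. The summaries were kept out of library sizes and tests. Of all counts, 8.22% to 16.8% fell in no feature, 0.576% to 0.764% were ambiguous and 10.3% to 13.5% were not unique.

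Of the 37621 feature IDs, 32897 matched a symbol in the reference gene table, and the others kept their ID. That table and the transcripts belong to a GENCODE annotation of assembly GRCm38 while the counts were made on mm9, so genes were matched by ID and no positions are printed. The 10 most abundant genes held 2.38% to 3.08% of the gene counts of a library. Within groups, replicate pairs had a chi-square per degree of freedom of 6.97 to 60.0 over 24 pairs, so no library was a copy of another in its group.

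Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Biostrings 2.70.1. The choices that follow were made before the data were examined unless stated otherwise. Genes were filtered with filterByExpr, scaled with TMM factors and tested with the edgeR quasi-likelihood F test (robust=TRUE), knockout minus wild type. Each region was tested on its own 6 libraries. The knockout effect averaged over the 4 regions and the difference of that effect between regions (the interaction) were tested on all 24 libraries. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and an adjusted p under 0.05 was called a change. Log2 fold changes (log2) are given with their standard error (SE).

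Gene lists were fixed beforehand: 32 lists with 444 symbols, of which 441 were matched, 6 of them through a synonym. They covered immediate-early genes, feedback genes of the MAP kinase pathway, late activity-response genes, clock genes, reported miR-7 targets, hosts and partners of the Cdr1as network, glutamate receptors, GABA-A receptors, synaptic vesicle release, glucocorticoid response, heat shock, interferon response, serotonin and dopamine signalling, nuclear oxidative phosphorylation and sex-linked genes. Marker lists covered excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, choroid plexus, meningeal fibroblasts, ependyma, erythrocytes, cerebellum, cortex, hippocampus, olfactory bulb, striatum and thalamus. Each list with at least 3 measured members was tested with camera (preset correlation of 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

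Genes are named by a fixed rule. These are, in each comparison, up to 10 per direction with the largest log2 among genes that passed, had at least 1 CPM and had groups that did not overlap (for the mean, the same sign in all 4 regions). Where fewer than 5 passed, the 5 with the smallest p are given as values that did not pass. From the immediate-early, clock and miR-7 target lists come the members that passed, at most 12, and from any other called list up to 4 members with the smallest p. The genes of the deleted locus and the 10 smallest interaction p complete the rule, and predicted genes without a name are replaced by the next named gene. Genes named outside the rule are marked as chosen after their values were seen. CPM are scaled with the TMM factors and given as mean ± SD of 3 libraries.

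The replicate number within the region was used as a block (paired fit) in a second run of each comparison. Pairing was checked by correlating, over genes, the deviations of knockout and wild-type libraries of equal number. These correlations were 0.211 to 0.642 in the cerebellum, 0.310 to 0.590 in the hippocampus and 0.213 to 0.725 in the olfactory bulb, where equal numbers were taken as pairs. Unequal numbers reached 0.285, 0.316 and 0.401 in these regions, above some equal ones, and only number 2 stood clearly apart, so the pairing of numbers 1 and 3 is uncertain. In the cortex equal numbers gave -0.0943 to 0.629, and the pairing was not accepted. The block fits on average and for the interaction nevertheless include the cortex pairs. Further alternatives were other scaling, filters, tools and weights, leaving out each library, and duplicateCorrelation over libraries sharing genotype and number. Removing libraries numbered 2, removing the choroid-plexus-rich hippocampus libraries, removing the cortex, and averaging or summing over regions were chosen after the data had been seen.

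Matches to miR-7 and miR-671-5p were sought in annotated 3' UTRs, as the 7-base match to the seed and next base, with or without the A that makes 8. The median log2 of genes with a match minus that of genes without was compared with the same difference for heptamers of the same base composition. Transcripts carried no UTR bounds, so these were built from the annotation.

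The code was tested on simulated data. Counts were drawn for each library independently, with means and dispersions from the deposited counts, so correlation between libraries was not simulated. For the site test, log2 values were drawn as independent normal values with the observed spread, so their tie to 3' UTR content was not simulated. In 15692 cortex genes edgeR found 44.8%, 82.1% and 100% of genes changed 1.5-, 2- and 4-fold, with 20 false among 171 calls. In the hippocampus it found 34.3%, 79.1% and 95.4%, with 12 false among 150. For the mean of the regions it found 86.6%, 97.0% and 100%, with 8 false among 197, and for the interaction 16.4%, 59.7% and 92.4%, with 3 false among 115. These shares may overstate what the deposited libraries of a single region can detect. Cdr1asG, at 3.40% to 11.3% of its wild-type CPM in the knockout, passed in no single region in edgeR without the block. With camera the raised list was found in all 3 runs and 0 of 20 lists without a change were called. Genes were drawn independently of each other, and the raised list held only genes raised 1.5- to 4-fold. The list test was therefore not tried on members that move together, nor on small shifts. A shift of 0.05 in genes with a site came back as 0.0512 and had an unadjusted p under 0.05 in 10 of 10 draws, against 1 of 10 without a shift. Detection after adjustment over the site tests was not simulated.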

Results

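Poly(A)-selected RNA was measured in the cerebellum, cortex, hippocampus and olfactory bulb of Cdr1as-knockout and wild-type mice, with 3 libraries in each of 8 groups. Library depth was 21.1 M to 40.5 M gene counts, and 19220 to 21159 features had at least 1 count. In the olfactory bulb the knockout libraries were deeper (33.8 M to 40.5 M) than the wild-type ones (21.1 M to 27.2 M). Replicates are not stated to be separate animals, so the p-values measure the spread between these samples. Marker genes separated the regions. In wild-type tissue the cerebellum markers averaged 8.79 log2 CPM in the cerebellum and at most 1.85 elsewhere, and the bulb markers averaged 7.25 in the bulb, 3.20 in the cortex and 0.49 in the cerebellum. Cortex markers averaged 5.82 in the cortex against 4.36 in the hippocampus, and hippocampus markers 6.84 in the hippocampus against 3.61 in the cortex.

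Was the Cdr1as locus silent in the knockout? Cdr1as is a circular RNA known for its many binding sites for miR-7. A circle has no poly(A) tail, so values from poly(A)-selected RNA do not measure its abundance. The feature Cdr1asG had 18 ± 11.7 CPM in wild-type cerebellum, 6.24 ± 3.31 in cortex, 7.69 ± 5.17 in hippocampus and 7.41 ± 4.53 in bulb. In the knockout 0.611 ± 0.393, 0.311 ± 0.160, 0.869 ± 0.926 and 0.357 ± 0.266 CPM remained. Cdr1asG fell on average over the regions (log2 -4.19, SE 0.45, edgeR adjusted p = 4.41e-05) and was lower in all 12 pairs of equal number. Within single regions it did not pass in edgeR (log2 -4.86, -4.36, -3.20 and -4.38 in the order above, adjusted p = 0.499, 0.0844, 0.954 and 0.583). With the replicate block it passed in the cerebellum (adjusted p = 0.000487) and the bulb (0.000289). Wild-type replicate 2 had the lowest value of its group in every region. The protein-coding annotation Cdr1 had 0 or 1 count per library.

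C230004F18Rik, a long noncoding RNA annotated across Cdr1 on the opposite strand of the X chromosome in GRCm38, moved the other way. It rose on average over the regions (log2 0.92, SE 0.19, edgeR adjusted p = 0.0106) and was higher in 11 of 12 pairs. Its CPM went from 8.57 ± 1.40 to 19.3 ± 2.54 in the cortex, from 11.7 ± 2.26 to 19.4 ± 10.3 in the cerebellum, from 10.1 ± 1.36 to 22.1 ± 11.5 in the hippocampus and from 9.98 ± 1.72 to 15.6 ± 8.14 in the bulb. The log2 was 0.74 in the cerebellum, 1.13 in the hippocampus and 0.64 in the bulb, but 0.25 in the cerebellum and 0.63 in the hippocampus without knockout 3 and 0.16 in the bulb without knockout 1. No single region passed (the smallest adjusted p was 0.0726, in the cortex, edgeR), and without the cortex the average was 0.84 (adjusted p = 0.122). Of 9 other tested genes within 3 Mb, 0 passed on average over the regions, and the 5 with at least 1 CPM lay between -0.12 and 0.15. Among those under 1 CPM, Sox3, the developmental transcription factor, chosen after its value was seen, was at 0.56 (SE 0.19, edgeR adjusted p = 0.156). Cdr1, on the opposite strand, had at most 1 count per library. Neither the place of Cdr1asG nor the strand setting of the counting is known here. How reads in a shared stretch were assigned is therefore open, and the size of this rise is uncertain.

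**Figure D1:**
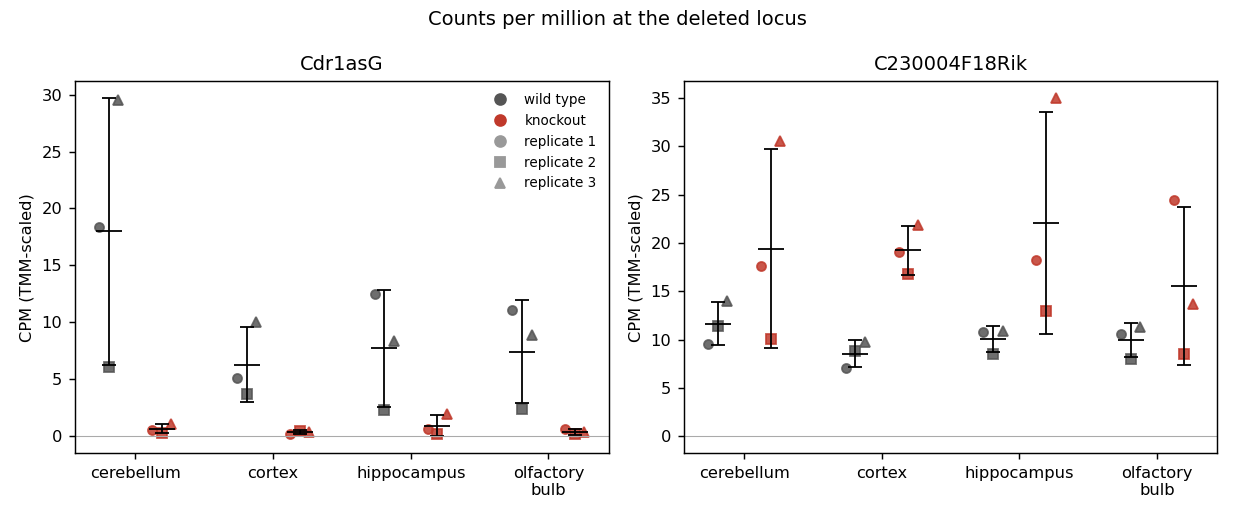
CPM of Cdr1asG and C230004F18Rik in each library, by region and genotype, with bars at the group mean ± SD and symbols for the replicate number. Cdr1asG is near 0 in knockout libraries, while C230004F18Rik tends to lie higher.

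Which genes changed when the 4 regions were averaged? Among 17266 genes, 313 rose and 149 fell (edgeR), and 437 of these 462 had the same sign in every region, which choosing genes by their average favours. The p-values on average, here and for Cdr1asG and C230004F18Rik above, treat the 24 libraries as independent. When libraries sharing genotype and number were averaged over the regions, 0 genes passed without the replicate block. The largest rises were those of Fos (1.95, SE 0.26, adjusted p = 0.000319), Fosb (1.56, SE 0.19, 9.88e-05) and Npas4 (1.55, SE 0.23, 0.000863), transcription factors switched on within minutes by neuronal activity. The orphan nuclear receptors Nr4a3 (1.52) and Nr4a1 (1.34), the stress-responsive factor Atf3 (1.32), Fosl2 (1.15), and Egr4 (1.13) rose as well. Fos was higher in every region (2.30, 1.90, 2.01 and 1.61 in cerebellum, cortex, hippocampus and bulb), as was Npas4 (1.67, 1.53, 1.60 and 1.38). Tmem252 (1.52), a membrane protein of little known function, and Tnfrsf25 (1.27), a death receptor of the TNF family, rose in the same measure. Both were higher in all 12 pairs. The 30 of 43 measured immediate-early genes that rose had no counterpart that fell. The list median was 0.66, 41 members were higher, and the camera adjusted p was 1.26e-44 (adjusted p = 0.00873 with an estimated correlation), with 37 past the threshold when adjusted over the list alone. Klf4 (0.93), Sik1 (0.92), Tiparp (0.69), Gadd45b (0.59) and Midn (0.47) were among them. This group was known to have been examined in this knockout, so its direction is not independent evidence.

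Genes that feed back on MAP kinase signalling, which acts upstream of Fos and Egr genes, rose too. Of 14 measured, 5 rose and 0 fell: Spry4 (0.55), Errfi1 (0.43), Dusp4 (0.41), Dusp6 (0.34) and Spred2 (0.22, chosen after its value was seen). The list median was 0.077 (camera adjusted p = 0.000691, and adjusted p = 0.0458 with an estimated correlation, but 0.249 with an estimated correlation in the replicate block fit). Among 24 clock genes 5 rose and 2 fell while the list as a whole did not pass (median 0.034, camera adjusted p = 0.428). Per1 (0.79, SE 0.084), the D-box repressor Nfil3 (0.65), Per2 (0.36), Bhlhe40 (0.22) and Arntl (0.17) rose, and the D-box activator Dbp (-0.63, SE 0.075) and Bhlhe41 (-0.22) fell. Bhlhe40 lost its call without the cortex (log2 0.042, adjusted p = 0.845) and in 14 of 24 runs that left out 1 library (highest adjusted p 0.0645). Bhlhe41 (-0.25, 0.0530), Arntl (0.16, 0.0886) and, of the feedback genes, Dusp6 (0.28, 0.0659) also lost their call without the cortex.

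Reported miR-7 targets showed 4 rises among 25 measured and no fall: Klf4, Irs2 (0.57) and Irs1 (0.21), adaptors of insulin signalling, and the kinase Mknk2 (0.28). Their median was 0.028 (camera adjusted p = 0.00557, adjusted p = 0.145 with an estimated correlation). It was 0.043 without cerebellum wild-type 1, 0.045 without hippocampus wild-type 2, 0.017 without hippocampus knockout 2, 0.010 without the choroid-plexus-rich libraries and 0.054 without the cortex. Without the cortex Irs2 (0.50, edgeR adjusted p = 0.0651), Mknk2 (0.26, 0.0530) and Irs1 (0.20, 0.134) lost their calls at similar values, and only Klf4 kept it. Klf4 belongs to the immediate-early list as well, so its rise is not separate evidence for these targets. Irs1 also lost its call in 10 of 24 runs leaving out 1 library (highest adjusted p 0.0626).

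Among the falls, Xlr3b (-1.83, SE 0.31, edgeR adjusted p = 0.00222) and Xlr3a (-1.43, SE 0.31, 0.0163) belong to a family of close X-linked copies, so reads may be shared between them. Xlr3a lost its call without the choroid-plexus-rich libraries (-1.08, adjusted p = 0.140), without the cortex (-1.19, 0.177) and, at a larger fall of 1.698, without the libraries numbered 2 (0.0730). The apoptosis ligand Tnfsf10 fell by 0.86 (SE 0.086, 1.99e-05) and was lower in all 12 pairs. The endothelial lectin Clec14a (-0.85), the rhomboid-like Tmem82 (-0.99), the cilium gene Tekt4 (-0.81) and H3f3aos (-0.80), an antisense transcript whose counts are uncertain, fell too. Tekt4 lost its call without cerebellum wild-type 2 (-0.74, adjusted p = 0.0553), cerebellum knockout 3 (-0.75, 0.0539) or cortex wild-type 3 (-0.77, 0.0507), and further without the cortex (-0.73, 0.152) or the choroid-plexus-rich libraries (-0.75, 0.0875). Clic6 (-1.76, adjusted p = 0.0361), a choroid plexus channel, reached only 0.0833 in the replicate block fit and -0.59 (adjusted p = 0.498) without the choroid-plexus-rich libraries, and lost its call in 19 of 24 runs leaving out 1 library. Tbx21 (-0.84, adjusted p = 0.0494), a transcription factor of bulb projection neurons, lost its call in 18 of 24 such runs (highest adjusted p 0.322) and was -0.31 (adjusted p = 0.794) without the cortex.

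Markers of oligodendrocyte precursors were lower (median -0.16, camera adjusted p = 0.00185, adjusted p = 0.145 with an estimated correlation). Of 8 measured, 1 fell, the lineage factor Olig2 (-0.49, SE 0.067, edgeR adjusted p = 0.000212), which lay at -0.50, -0.50, -0.50 and -0.47 in the regions, while Cspg4 (-0.18), Pdgfra (-0.17) and Olig1 (-0.15) did not pass. In the replicate block fit Pdgfra (edgeR adjusted p = 0.0417) and Cspg4 (0.0492) passed, as did Cbln1 (0.0472), Pax6 (0.0351) and the dopamine synthesis gene Th (0.02) of the region markers. The median was -0.10 without the choroid-plexus-rich libraries. Of 12 microglia markers 0 passed and 11 were lower, including C1qb (-0.22) and Cx3cr1 (-0.14), with a median of -0.11 (camera adjusted p = 0.0166, adjusted p = 0.864 with an estimated correlation). That call ended without cerebellum wild-type 1 (-0.094, 0.0555), cerebellum knockout 1 (-0.10, 0.0605), cortex wild-type 1 (-0.091, 0.0791), cortex knockout 2 (-0.088, 0.0761) or bulb wild-type 2 (-0.068, 0.114). Cerebellum markers had 0 of 11 past the threshold and 8 lower, among them Zic1 (-0.33) and Cbln1 (-0.31), with a median of -0.17 (camera adjusted p = 0.0202, adjusted p = 0.270 with an estimated correlation). Their call ended without cerebellum knockout 1 (-0.16, 0.0511), cortex knockout 2 (-0.16, 0.0761), bulb knockout 3 (-0.16, 0.0552) or the cortex (-0.11, 0.171), and their median was also -0.11 without the libraries numbered 2. Of 11 bulb markers 1 fell (Tbx21) and 10 were lower (median -0.33, camera adjusted p = 0.00159, adjusted p = 0.413 with an estimated correlation). Without the cortex that median was -0.12 (adjusted p = 0.574). Choroid plexus markers (median -1.50) passed only in the replicate block fit (camera adjusted p = 0.174, and 0.000663 with the block, adjusted p = 0.724 with an estimated correlation).

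The number of genes depended on how the libraries were treated: DESeq2 gave 790 (462 shared), limma-voom 474, the replicate block 1256 (458 shared), and library totals in place of TMM 206 rises and 171 falls. Treating libraries that share genotype and number as correlated gave 108, all shared, averages over the regions gave 0 (164 with the replicate block, 127 shared), removing the cortex gave 217 (185 shared) with 13 named genes no longer called, and removing the libraries numbered 2 gave 200 (147 shared) with 17 no longer called, among them Fos (1.68, adjusted p = 0.0948) and Nr4a1 (adjusted p = 0.256). The others that lost their call without the libraries numbered 2, at values of the same sign, included Fosb (1.36, edgeR adjusted p = 0.0649), Nr4a2 (0.0552), Sik1 (0.75, 0.0587), Egr4 (0.0918), Tmem252 (1.38, 0.0612), Tiparp (0.58, 0.0999), Dusp4 (0.34, 0.113), Dusp6 (0.31, 0.122) and Per2 (0.35, 0.104).

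**Figure D2:**
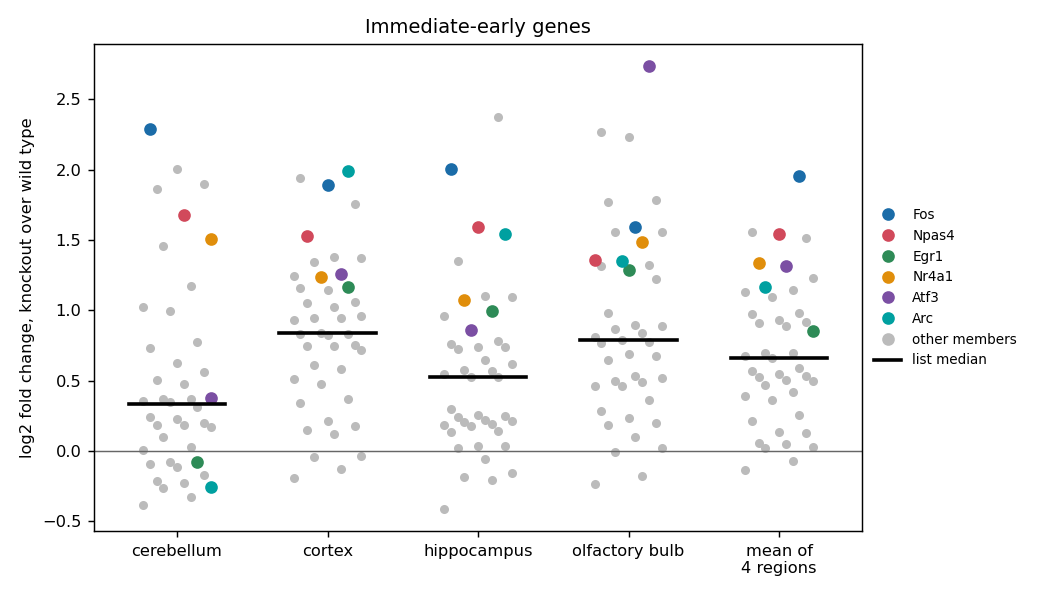
Log2 fold change of each immediate-early gene by region, with a line at the list median and Fos, Npas4, Egr1, Nr4a1, Atf3 and Arc in colour. Medians lie above 0 in all 4 regions.

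What changed in the cerebellum? In edgeR 0 of 15723 genes passed, 862 had an unadjusted p under 0.05 and the smallest adjusted p was 0.412. DESeq2 called 46 genes (29 up, 17 down) and limma-voom 0. The smallest p-values belonged to Trib1 (0.63, SE 0.083), a pseudokinase, Nfil3 (0.64), the Wnt inhibitor Apcdd1 (-0.65), the MAP kinase inhibitor Spry4 (0.99) and the nuclease Dnase1l2 (0.70). With the replicate block 3 genes passed: Cdr1asG down, and Fos and Nr4a2 up. Immediate-early genes had 0 of 42 past the threshold over all genes and 10 when adjusted over the list alone, including Fos (2.29), Nr4a3 (1.90), Nr4a2 (1.86) and Npas4 (1.68), examples chosen after their values were seen, as was Fos above. The list median was 0.33 with 31 members higher (camera adjusted p = 7.35e-08, adjusted p = 0.640 with an estimated correlation), and 0.21 without the libraries numbered 2. Arc (-0.25) and Egr1 (-0.078), 2 classical members chosen after their values were seen, were not higher here.

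Precursor markers were lower in the cerebellum as well (0 of 8 passed, 2 when adjusted over the list alone, 7 lower, median -0.26, camera adjusted p = 0.00192, adjusted p = 0.640 with an estimated correlation), with Olig2 at -0.50 and Olig1 at -0.33. Of 13 heat shock genes 0 passed and 9 were higher, with the co-chaperones Dnajb1 (0.58) and Bag3 (0.42) at the top (median 0.081, camera adjusted p = 0.0187, adjusted p = 0.828 with an estimated correlation). Leaving out wild-type 1 gave 0.52 and knockout 2 gave 0.21. The call ended without wild-type 2 (-0.048, 0.598), wild-type 3 (0.064, 0.202), knockout 3 (0.014, 0.182) or both number 2 (0.075, 0.105). Ependyma markers had 0 of 8 past the threshold and 7 lower, such as the dynein gene Dynlrb2 (-0.92) and Foxj1 (-0.31), with a median of -0.36 (camera adjusted p = 0.0187, adjusted p = 0.828 with an estimated correlation). Their median was -0.69 without knockout 2 and -0.71 without both number 2, and the call ended without wild-type 1 (-0.18, 0.162), knockout 1 (-0.23, 0.149) or knockout 3 (-0.11, 0.194). Microglia markers had 0 of 12 past the threshold and 11 lower, with C1qb at -0.24 and Tmem119 at -0.19 (median -0.13, camera adjusted p = 0.0307, adjusted p = 0.828 with an estimated correlation). That call ended without wild-type 1 (-0.060, 0.403), knockout 1 (-0.093, 0.422) or knockout 2 (-0.14, 0.0540). With the replicate block 3 further lists passed in camera: MAP kinase feedback (median 0.12, adjusted p from 0.0511 to 0.0449), excitatory neurons (-0.18, from 0.553 to 0.0283) and cerebellum markers (-0.049, from 0.0625 to 0.0449), each with adjusted p = 0.774 with an estimated correlation.

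What changed in the cortex? The 6 genes that passed in edgeR, of 15834 tested, all rose. Per1 (0.96, SE 0.087, adjusted p = 0.0262), a clock gene that activity also induces, went from 85.8 ± 4.89 to 167 ± 10.3 CPM. Egr1 (1.16, SE 0.12, 0.0391), a transcription factor of activity-driven plasticity, went from 213 ± 2.84 to 477 ± 85.4. The kinase Sik1 (1.38, SE 0.15, 0.0391), Egr4 (1.15, SE 0.13, 0.0398), Nr4a2 (0.74, SE 0.087, 0.0410) and Nab2 (0.77, SE 0.093, 0.0451), a repressor that holds back Egr factors, completed the set. The calls, though not the size of the changes, depended on single libraries: over the runs leaving out 1 library log2 stayed at 0.91 to 1.02 for Per1, 0.70 to 0.79 for Nr4a2 and 1.28 to 1.51 for Sik1. Without wild-type 1, 4 genes passed, of which 2 were among the 6, and without wild-type 2, 3 passed, of which 1 was among them, while 0 passed without wild-type 3, knockout 1, knockout 2 or knockout 3 (highest adjusted p 0.192 for Per1 and 0.368 for Nr4a2). Without both number 2, 4 genes passed, of which 2 were among the 6, and Sik1, Egr4, Nr4a2 and Nab2 lost their call (highest adjusted p 0.194). DESeq2 called 102 genes (77 up, 25 down), limma-voom 6, voomWithQualityWeights 44, edgeR without a filter 28, all 24 libraries in 1 fit 49, robust=FALSE 1 and library totals 0.

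Immediate-early genes in the cortex had 4 of 43 rises over all genes and 32 when adjusted over the list alone, with 39 members higher and a median of 0.84 (camera adjusted p = 1.92e-53, adjusted p = 0.158 with an estimated correlation). MAP kinase feedback genes showed 0 of 14 past the threshold and 13 higher, including Dusp4 (0.55), Dusp6 (0.50) and Spry4 (0.44), with a median of 0.12, or 0.19 without wild-type 1 (camera adjusted p = 0.000167, adjusted p = 0.241 with an estimated correlation). Reported miR-7 targets had 0 of 25 past the threshold and 16 higher, Klf4 (1.24, chosen after its value was seen) the most (median 0.042, camera adjusted p = 0.0146, adjusted p = 0.571 with an estimated correlation). Their median was 0.093, 0.023, 0.088 and 0.069 without wild-type 1, wild-type 3, knockout 2 and knockout 3, and the call ended without wild-type 2 (0.10, 0.0959). The 6 measured genes of the Cdr1as network, with C230004F18Rik (1.16), Ago1 (0.19) and Hnrnpk (-0.025), had 0 past the threshold, a median of 0.015 and a camera adjusted p of 0.0393 (adjusted p = 0.345 with an estimated correlation). Their median turned negative with library totals (-0.0026) and without knockout 1 (-0.0018, 0.0504) or knockout 3 (-0.0073, 0.0592). It was 0.082 without wild-type 3 and without knockout 2, and the call also ended without wild-type 1 (0.099, 0.0864), wild-type 2 (0.064, 0.141) or both number 2 (0.028, 0.0705).

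Cell-type markers of the cortex moved in small steps and 0 passed over all genes in any of these lists. Excitatory neuron markers had 9 of 10 higher, with Neurod2 at 0.47 and Slc17a7 at 0.13 (median 0.10, camera adjusted p = 0.0307, adjusted p = 0.581 with an estimated correlation). Their median was 0.16 without wild-type 1 and 0.17 without knockout 2, and the call ended without wild-type 2 (0.10, 0.116), wild-type 3 (0.053, 0.198), knockout 1 (0.040, 0.238) or knockout 3 (0.074, 0.0884). Inhibitory neuron markers had 12 of 12 lower, with Calb2 at -1.06, Dlx1 at -0.41 and Gad2 at -0.29 (median -0.16, or -0.090 without wild-type 1, camera adjusted p = 0.000167, adjusted p = 0.571 with an estimated correlation). Oligodendrocyte markers had 11 of 12 lower, such as the myelin genes Mog (-0.24) and Cldn11 (-0.15), with a median of -0.11 (camera adjusted p = 0.0307, adjusted p = 0.719 with an estimated correlation). Their median was -0.18 without wild-type 2 and -0.21 without both number 2, and the call ended without wild-type 1 (-0.099, 0.0650), wild-type 3 (-0.043, 0.419) or knockout 3 (-0.037, 0.507). Precursor markers had 7 of 8 lower, Olig2 again at -0.51 (median -0.19, camera adjusted p = 0.00842, adjusted p = 0.345 with an estimated correlation), and the call ended without wild-type 1 (-0.14, 0.157).

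Markers of the bulb, thalamus and cerebellum were lower in the knockout cortex. Bulb markers had 11 of 11 lower and 8 past the threshold when adjusted over the list alone, with Eomes at -3.74, Tbx21 at -2.41 and Sp8 at -1.18 (median -1.05, or -0.63 without wild-type 1, camera adjusted p = 1.96e-14, adjusted p = 0.345 with an estimated correlation). Thalamus markers had 9 of 9 lower, with Prkcd at -1.09 and Synpo2 at -0.81 (median -0.23, camera adjusted p = 0.00127, adjusted p = 0.571 with an estimated correlation). Their median was -0.38 without wild-type 1 or wild-type 2, -0.36 without knockout 1 and -0.40 without both number 2, and the call ended without wild-type 3 (-0.044, 0.363). Cerebellum markers had 7 of 9 lower, with Zic1 at -0.98 and Pax6 at -0.34 (median -0.24, camera adjusted p = 0.0215, adjusted p = 0.345 with an estimated correlation), and the call ended without wild-type 1 (-0.19, 0.0735), knockout 2 (-0.15, 0.113) or both number 2 (-0.20, 0.0543). Genes of the bulb also sit in the other lists. Calb2, Dlx1 and Dlx2 belong to both the bulb and the inhibitory list, and Calb2 to the thalamus list as well. The inhibitory and thalamus results are therefore not separate from that of the bulb list. Calb2 had 532 CPM in wild-type bulb and 47.6 in wild-type cortex, and Zic1, in the cerebellum list, had 149 and 32.8.

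What changed in the hippocampus? In edgeR 0 of 15572 genes passed, 804 had an unadjusted p under 0.05 and the smallest adjusted p was 0.542, against 37 calls in DESeq2 (18 up, 19 down) and 0 in limma-voom. The smallest p-values belonged to Tnfrsf25 (1.24, SE 0.14), the interleukin receptor Il1r1 (0.66), Plekho2 (-0.84), a signalling adaptor, the EGF receptor inhibitor Errfi1 (0.69) and Egr4 (1.35). With the replicate block 15 genes passed (7 up, 8 down), among them Tnfrsf25 and Egr4 (adjusted p = 0.000766 each) and Il1r1 and Plekho2 (0.0469 each). Leaving out wild-type 2 gave 42 falls and no rise, and leaving out both number 2 gave 4 rises and 95 falls. Immediate-early genes had 0 of 43 past the threshold over all genes and 11 when adjusted over the list alone, including Egr2 (2.37), Fos (2.01), Npas4 (1.60) and Arc (1.54), chosen after their values were seen. Their median was 0.53 with 38 higher (camera adjusted p = 7.19e-16, adjusted p = 0.871 with an estimated correlation), but 0.25 without knockout 2 and 0.20 without both number 2.

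The choroid plexus markers of the hippocampus had 0 of 10 past the threshold over all genes and 10 when adjusted over the list alone. The thyroxine carrier Ttr had 1710 ± 1517 CPM in wild-type and 9.17 ± 3.15 in knockout tissue (log2 -7.54), F5 was at -5.34 and the water channel Aqp1 at -4.08. Their median was -4.07 (camera adjusted p = 0.000328, adjusted p = 0.871 with an estimated correlation), and 0.47 (0.324) without the 2 choroid-plexus-rich wild-type libraries. Meningeal fibroblast markers had 0 of 10 past the threshold and 8 lower, with Dcn at -1.06 and Igf2 at -0.80 (median -0.37, camera adjusted p = 0.00791, adjusted p = 0.871 with an estimated correlation, 0.0563 with the replicate block). Their median was -0.86 without knockout 2 and -0.94 without both number 2, and the call ended without wild-type 3 (-0.21, 0.111), knockout 1 (-0.22, 0.0868), knockout 3 (-0.24, 0.305) or the choroid-plexus-rich libraries (-0.10, 0.306). Striatum markers had 0 of 10 past the threshold and 7 lower, with the dopamine receptor Drd1 at -0.80 and Ppp1r1b at -0.37 (median -0.32, camera adjusted p = 0.0404, adjusted p = 0.871 with an estimated correlation, 0.0609 with the replicate block). That call ended without wild-type 1 (-0.27, 0.0505), wild-type 2 (-0.39, 0.0509), wild-type 3 (-0.17, 0.111), knockout 1 (-0.27, 0.0579), knockout 3 (-0.40, 0.132) or the choroid-plexus-rich libraries (-0.042, 0.324). Thalamus markers had 0 of 9 past the threshold and 8 higher, with Tnnt1 at 1.94 and Tcf7l2 at 1.17 (median 0.40, camera adjusted p = 0.0301, adjusted p = 0.871 with an estimated correlation). Their median was 0.67 without the choroid-plexus-rich libraries, and the call ended without wild-type 2 (0.47, 0.235), knockout 2 (0.053, 0.914) or both number 2 (-0.037, 0.917).

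What changed in the olfactory bulb? In edgeR 0 of 16131 genes passed, 859 had an unadjusted p under 0.05 and the smallest adjusted p was 0.259, against 60 calls in DESeq2 (50 up, 10 down) and 0 in limma-voom. With the replicate block 57 genes passed (51 up, 6 down). The smallest p-values belonged to genes that passed in that paired fit: Egr3 (1.56, SE 0.16, adjusted p = 0.000289 with the block), Atf3 (2.74, SE 0.31, 0.000200), Nr4a2 (1.56, 0.000200), Arid5a (0.98, 0.0113), a protein that stabilizes cytokine mRNA, and Spata2l (0.72, 0.0108). Immediate-early genes had 0 of 43 past the threshold over all genes and 29 when adjusted over the list alone, including Fosb (2.27), Nr4a3 (2.23), Fosl2 (1.79) and Egr1 (1.29), chosen after their values were seen. Their median was 0.79 with 40 higher (camera adjusted p = 1.52e-39, adjusted p = 0.277 with an estimated correlation).

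MAP kinase feedback genes of the bulb had 0 of 14 past the threshold, 5 when adjusted over the list alone and 10 higher, with Spry4 at 0.61 (0.0159 with the replicate block) and Dusp4 and Dusp6 at 0.41 (median 0.13, camera adjusted p = 0.000259, adjusted p = 0.277 with an estimated correlation). Late activity-response genes had 0 of 18 past the threshold and 15 higher, such as the synaptic pentraxin Nptx2 (0.24) and Rheb (0.22), with a median of 0.18 (camera adjusted p = 0.0223, adjusted p = 0.748 with an estimated correlation). The call ended without wild-type 2 (0.093, 0.374), knockout 1 (0.10, 0.0795), knockout 3 (0.14, 0.0712) or both number 2 (0.10, 0.0527). Reported miR-7 targets had 0 of 25 past the threshold and 18 higher (median 0.052, camera adjusted p = 0.0154, adjusted p = 0.277 with an estimated correlation), and the call ended without wild-type 3 (0.037, 0.0598) or knockout 1 (0.043, 0.0501). Vesicle release genes had 0 of 29 past the threshold and 23 higher, with Syt2 (0.40) and Syt4 (0.34) at the top (median 0.062, camera adjusted p = 0.0165, adjusted p = 0.748 with an estimated correlation). Their median was 0.12 without wild-type 1, and the call ended without wild-type 2 (0.075, 0.174), wild-type 3 (0.031, 0.132), knockout 1 (0.050, 0.176) or knockout 3 (0.069, 0.0526). Excitatory neuron markers had 0 of 10 past the threshold and 9 higher, with Camk2a at 0.22 and Nrgn at 0.17 (median 0.18, camera adjusted p = 0.0333, adjusted p = 0.748 with an estimated correlation), and the call ended without wild-type 2 (0.16, 0.189), wild-type 3 (0.21, 0.0605) or knockout 1 (0.023, 0.752). Microglia markers had 0 of 12 past the threshold and 12 lower, with the complement genes C1qb at -0.40 and C1qc at -0.36 (median -0.19, camera adjusted p = 0.00259, adjusted p = 0.748 with an estimated correlation), and the call ended without wild-type 2 (-0.11, 0.334) or both number 2 (-0.058, 0.374). With the replicate block 3 further lists passed in camera: glutamate receptors (median 0.082, adjusted p from 0.156 to 0.0460), bulb markers (-0.025, from 0.0659 to 0.0460) and nuclear oxidative phosphorylation (-0.058, from 0.0608 to 0.0460), with adjusted p = 0.607, 0.607 and 0.787 with an estimated correlation.

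Did the knockout effect differ between the regions? In the edgeR interaction test 4 of 17266 genes passed and 439 had an unadjusted p under 0.05, against 39 in DESeq2, 3 in limma-voom and 11 with the replicate block (3 shared). The nearest genes that did not pass were Atf3 (adjusted p = 0.0649), Bhlhe40 (0.0753), the stress-induced Ier5 (0.0753), Lonrf1 (0.0909), and Irf2bpl, Tbx21 and Ms4a15 (0.0988 each). Tbx21 (-2.40) and Ms4a15 (-4.12) were lowest in the cortex and are genes restricted to the bulb. In the replicate block fit Atf3 (edgeR adjusted p = 0.00893), Bhlhe40 (0.00627), Ier5 (0.00726) and Irf2bpl (0.0126) passed, as did Gadd45b (0.0119), Nr4a2 (0.0179) and Th (0.0126), so whether these vary between the regions depends on the pairing. Fos and Npas4 passed in neither fit and are not shown to differ between the regions. On average over the regions Rara (0.24, adjusted p = 0.0794, 0.0222 with the block) and Ier5 (0.14, 0.188, 0.0252 with the block) passed only in the paired fit. The count moved from 0 without cortex knockout 1 to 21 without hippocampus wild-type 2, with 2 without cerebellum wild-type 1, 1 without cerebellum wild-type 2 and 2 without cortex wild-type 3.

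How did the lists without a call in the unpaired fits behave? On average over the regions the GABA-A receptors (median -0.044, camera adjusted p = 0.744) and serotonin and dopamine genes (-0.019, 0.916) did not pass. The interferon genes (-0.15, 0.249) contained 1 rise, the signal transducer Irf9 (0.37). Glucocorticoid response genes had 2 rises and 2 falls (median 0.072, mean -0.0067, camera adjusted p = 0.398). The metabolic kinase Pdk4 (0.47) rose and the metallothioneins Mt2 (-0.44) and Mt1 (-0.27) fell, all 3 named as values chosen after they were seen, as were Irf9, Kdr and Ly6c1. Astrocyte markers had a median of 0.0012 but a mean of -0.062 and a downward test (0.338). Endothelial markers (-0.032, 0.216) contained 2 falls, the growth factor receptor Kdr (-0.30) and Ly6c1 (-0.24). Erythrocyte (0.065, 0.640), hippocampus (0.049, 0.751) and cortex markers (-0.015 with an upward test, 0.910) did not pass, nor did the sex-linked genes (0.034, 0.807).

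Lists called only in some regions, or there only with the replicate block, gave these averages over the 4 regions, 0 of them past the threshold in camera. Heat shock genes had a median of -0.0021 but a mean of 0.071 (adjusted p = 0.174), with 1 rise, Dnajb1 (0.51, chosen after its value was seen). The Cdr1as network genes were at 0.053 (0.281), glutamate receptors at 0.030 (0.744), vesicle release at 0.024 (0.249), nuclear oxidative phosphorylation at -0.029 (0.174) and late activity-response genes at -0.010 with an upward test (0.640). Excitatory neuron markers were at 0.024 (0.639), inhibitory neuron markers at -0.078 (0.174) and oligodendrocyte markers at -0.020 with a mean of 0.0022 (0.855). Meningeal fibroblast (-0.14, 0.313), ependyma (-0.15, 0.174) and striatum markers (-0.17, 0.249) were lower, and thalamus markers were at 0.055 with a downward test (0.982).

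Did genes with miR-7 sites move as a group? Of 15168 tested genes with an annotated 3' UTR, 2093 had a match to miR-7 and 13075 did not. Their medians differed by 0.012 on average over the regions, below the 0.018 that 79 heptamers of the same composition gave at the middle (exact rank p = 0.0375, 0.125 when adjusted over the 10 site tests). The difference was 0.0093 in the cortex (heptamers 0.020, adjusted p = 0.0625), 0.015 in the bulb (0.025, 0.0625), 0.015 in the cerebellum (0.018, 0.458) and -0.0017 in the hippocampus (0.0028, 0.433). In the cortex and the bulb the difference lay below that of every heptamer (lowest 0.0117 and 0.0166), so genes with a miR-7 match were not higher there than genes with other heptamers. With 79 heptamers the smallest exact rank p is 0.0125, which a single test could not carry past the adjustment, so a missing call does not exclude an effect. For miR-671-5p, which has a nearly perfect site in Cdr1as, the 2165 genes with a match differed by 0.020 on average against 0.021 for its heptamers (exact rank p = 0.733). Within the immediate-early list the 8 genes with a miR-7 match lay above the others in the cerebellum (difference 0.28) and the bulb (0.26) and below them in the cortex (-0.46), the hippocampus (-0.40) and on average (-0.14). The smallest permutation p was 0.0484, in the cortex (0.242 when adjusted over the 5 permutation tests), so no direction is shown.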

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

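Tests of bulb tissue in the wild-type cortex and of lower bulb marker expression everywhere were chosen only after the result was seen. Bulb markers were lower in the knockout cortex, with a median of -1.05 in 11 genes. Bulb tissue in the wild-type cortex pieces may account for it. Of 13 genes restricted to the bulb, 100% were higher in wild-type cortex, Tbx21 and Ms4a15 among them. Restricted here meant at most 2% of the bulb level in wild-type hippocampus and cerebellum, while expression in the cortex was not limited. Trh had 80.7 CPM in wild-type bulb, 14.6 in wild-type cortex and 7.47 in knockout cortex. Tbx21, Trh and Sp8 also belong to the marker list, so the sets overlap. As a median over these genes, the wild-type cortex libraries held 1.94% to 2.99% of the bulb level and the knockout ones 0.440% to 0.816%. The difference between the genotypes had a median of 1.68% of the bulb level, from 0.140% (Cyp2a5) to 8.84% (Trh). A lower expression of these markers in the knockout wherever they are expressed is argued against by their median of -0.025 in the bulb itself. At the median share of 1.68%, bulb tissue would cover only part of the cortex falls of Calb2 and Zic1, whose levels are given above. How far the inhibitory, cerebellum and thalamus markers of the cortex moved for the same reason stays open. Shares varied between genes, and dissection records are not used here.

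The knockout effect on Eomes varied between the regions (1.41, -3.72, 0.33 and -0.11 in cerebellum, cortex, hippocampus and bulb, edgeR interaction adjusted p = 0.0107). Eomes marks unipolar brush cells in the cerebellum, where it went from 27.7 to 73.4 CPM, and projection neurons in the bulb. Frmd7, itself among the 13 genes restricted to the bulb, gave -0.64, -2.03, 0.11 and 0.024 (edgeR adjusted p = 0.0201, 0.0715 with the replicate block). Rara, the retinoic acid receptor, gave -0.50, 0.91, 0.58 and -0.040 (edgeR adjusted p = 0.0201). The transcript 1190002N15Rik, chosen after its values were seen, gave -0.035, -0.45, -0.077 and 0.33 (edgeR adjusted p = 0.0319). Of 100 splits drawn within the regions, 8, the real one included, gave at least as many genes, with up to 172 in another split. These splits were drawn separately in each region, so an effect shared by the regions can appear in them as a difference between regions. They therefore cannot decide whether these 4 genes reflect the grouping of the samples alone, and chance is not excluded. Of the 4, 3 also passed with the replicate block.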

How the results depend on the processing

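Of 121 values of the immediate-early list under other choices, 121 kept their sign and 113 kept the call. These counts overstate the range of choices, for this list and for the other lists. Under robust=FALSE and limma-voom camera used the same values as the main run, so its p-values could not differ. All choices but the estimated correlation and fry kept the preset correlation of 0.01. The 8 weaker ones, with medians of 0.33, 0.84, 0.53 and 0.79, were the estimated correlation (adjusted p = 0.640, 0.158, 0.871 and 0.277 in cerebellum, cortex, hippocampus and bulb, camera) and fry (0.409, 0.0576, 0.833 and 0.101). Leaving out 1 library gave medians of 0.24 to 0.39 in cerebellum, 0.81 to 1.0 in cortex, 0.25 to 0.59 in hippocampus, 0.63 to 0.92 in bulb and 0.59 to 0.72 on average.

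Other tools and the replicate block moved counts of genes. DESeq2 gave 46 in cerebellum, 102 in cortex, 37 in hippocampus, 60 in bulb, 790 on average and 39 for the interaction. With voomWithQualityWeights there were 44 in cortex, 923 on average and 9 for the interaction. The replicate block gave 3, 110, 15 and 57 in the regions, 1256 on average and 11 for the interaction, and it changed no call of a list or named gene on average or in the 3 paired regions beyond those printed with the results. In the cortex the pairing correlation was -0.0943 to 0.629, so the block results of the cortex comparison are reported only in this section. In that comparison the block added GABA-A receptor, astrocyte, microglia, striatum and oxidative phosphorylation lists. The block fits on average, for the interaction and of the averages also used the cortex pairs. Their results thus rest in part on a pairing that was not accepted. In splits parting all same-number pairs, with the block (added after the data had been seen), the real split gave 3, 110, 15 and 57 genes, averages 164, and the highest other 0. Only 4 such splits exist, the real one included, too few for a share under 0.05, and in the cortex the pairing itself was not accepted.

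No filter gave 1 gene in cerebellum, 28 in cortex, 1 in hippocampus and 2 in bulb. All 24 libraries in 1 fit gave 2, 49, 5 and 20. Robust=FALSE left 1 in cortex and library totals 0. Without the libraries numbered 2 there were 4 in cortex (2 shared), 99 in hippocampus, 1 in bulb and 200 on average. Without the 2 choroid-plexus-rich libraries there were 294 on average and 1 for the interaction, and without the cortex 217 and 0. Leaving out 1 library gave 0 to 4 in cortex, 0 to 42 in hippocampus, 342 to 553 on average and 0 to 21 for the interaction.

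Libraries of equal genotype and number may share an animal. The knockout minus wild-type difference of each number, centred over the numbers, was correlated between regions. Equal numbers averaged 0.119 (lowest -0.105) and unequal ones -0.0594, which the centring pulls below 0. For cerebellum and cortex equal numbers averaged 0.349. Treating these libraries as independent is therefore doubtful, though a shared animal is not shown. With duplicateCorrelation (consensus 0.216) 108 genes passed on average, and with the replicate block added 692, and 25 for the interaction. Averages over the regions gave 0, or 164 with the block. Sums of counts gave 0, or 133 with the block. The sums were run first and the averages were added after their result was seen, because the deeper knockout bulb libraries weigh more in a sum. By that construction the bulb marker median on average turned to 0.34 and Tbx21 to 0.21 (0.20 with the block).

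Other reversals were few, and the cause was not tested. Heat shock in cerebellum turned to -0.048 without wild-type 2 (highest 0.52, without wild-type 1). The Cdr1as network list in cortex turned to -0.0026 with library totals, -0.0018 without knockout 1 and -0.0073 without knockout 3 (highest 0.099, without wild-type 1). The thalamus list in hippocampus turned to -0.037 without both number 2, and the choroid plexus list to 0.47 without its 2 rich libraries. Named genes that had passed kept their sign in 1864 of 1866 values and their call in 1567. Called lists kept their call in 581 of 724 values, with 135 weaker and 8 reversed. Uncalled lists were called in 172 of 3027 values, and uncalled named genes in 105 of 2460.

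For miR-7 sites 14 values were the same and 6 weaker, judged by the unadjusted exact rank p, which 3 tests met although 0 passed once adjusted over the 10 tests. With 8-base matches the difference was 0.0083 in cortex (exact rank p = 0.05) and 0.011 in bulb (0.1). With at least 2 sites it was 0.032 in cortex (exact rank p = 0.613), 0.022 in bulb (0.05) and 0.028 on average (0.5), and with at least 10 CPM 0.011 on average (0.0625).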

Other observations

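More genes of the Xlr family than the rule names were lower in the knockout. Xlr4b (-1.99, SE 0.44, edgeR adjusted p = 0.0150) and Xlr4a (-2.71, SE 0.66, 0.0310), chosen after their values were seen, fell on average over the regions together with Xlr3b and Xlr3a. The call of Xlr3a ended without the choroid-plexus-rich libraries, without the cortex and without the libraries numbered 2. Their abundance was low, at 0.381 and 0.517 CPM against 3.95 for Xlr3b and 1.79 for Xlr3a. These genes are close copies on the X chromosome, where the Cdr1as locus also lies, and reads counted for 1 copy may come from another.

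Tnfrsf25 was higher in each region (1.05, 1.87, 1.24 and 0.92 in cerebellum, cortex, hippocampus and bulb), and so was Tmem252 (1.38, 1.78, 1.44 and 1.47). Across 14437 genes the fold changes of a pair of regions correlated at 0.172 (hippocampus and bulb) to 0.338 (cortex and bulb), where genes are not independent replicates.

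For the immediate-early genes, the tests of neuron share, of a batch shared by equal numbers, of time of day and of miR-7 sites were chosen only after the result was seen. Immediate-early genes such as Fos, Fosb and Npas4 were higher in the knockout of every region. A larger share of neurons is argued against by the largest neuron list median of 0.18. Relief of miR-7 matches in these mRNAs alone is argued against by a median of 0.68 in the 35 members without a match. A match was the 7-base word in the longest annotated 3' UTR, so shorter or other sites in these 35 were not sought. Collection at another time of day stays open, since of 13 clock genes 11 had the sign of a single phase difference, with Dbp lower and Nfil3 higher, which could come from the knockout or from the hour of collection. These 13 were picked after the result was seen, only 4 of them passed, and they leave out Per1 (0.79) and Per2 (0.36), which rose while Per3 was at -0.19. List medians were above 0 in 12 of 12 same-number pairs (0.19 to 1.04), which does not test a shared batch, because every number holds both genotypes, and handling before death was not recorded in the labels.

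For C230004F18Rik, the test of the chromosome neighbourhood was chosen only after the result was seen, while the histone test was written before. C230004F18Rik was higher in the knockout while Cdr1asG was lower. A change of the whole neighbourhood is argued against by the largest log2 among the 5 genes of at least 1 CPM within 3 Mb, 0.15, but the nearest genes lie under that limit and were higher without passing (Sox3 at 0.56), so a change confined to them stays open. The median of 18 replication-dependent histone genes, -0.016, gave no sign of more RNA without a poly(A) tail in the knockout libraries. Whether the histone RNA counted here lacked a tail was not checked, so such a difference is not excluded. Between libraries numbered 2 and the others of a region, the mean log2 CPM of these genes differed by -0.410 to -0.158. Whether the deletion changed its promoter, its end or the reads assigned to it stays open.

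Splits of single regions and within the regions were written before the results were seen, and those of the averages, like the averages themselves, came after the data had been seen. Of 100 splits drawn within the regions, 1 (the real split) reached 462 genes on average over the regions, with 159 as the highest other, and 1 reached the immediate-early median of 0.66, with 0.32 as the highest other. These splits were drawn separately in each region, so they keep neither the pairs of equal number nor the correlation of libraries sharing genotype and number (0.216), and on the 6 averages the real split gave 0 genes, as did each other split. A single region has 10 splits, too few for a share under 0.05. The immediate-early medians of the real splits were 0.33, 0.84, 0.53 and 0.79 in cerebellum, cortex, hippocampus and bulb, and the highest other 0.29, 0.47, 0.43 and 0.61. In the averages over the regions the real split gave 0.63 and the highest other 0.45. The gene counts of the real splits were 0, 6, 0 and 0, and the highest other 0, 0, 0 and 1.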
